A study of Mus musculus with 4 samples.

How the data were processed

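Poly-A selected RNA was measured by sequencing in 4 libraries of mouse small intestinal organoids, which are epithelial cultures grown as small hollow bodies in a basement-membrane gel. Per the labels, 2 libraries came from organoids of adult C57BL/6 mice aged 4 to 8 weeks and 2 from organoids of embryos at embryonic day 15.5, all kept in the same commercial medium. The labels say nothing about separate animals or cultures behind the 2 replicates of a group, so p-values measure only the spread between these libraries, which may be technical.

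The first deposited table holds estimated counts (RSEM expected counts) per Ensembl gene for each library, per the file headers, with no normalization. The second deposited table holds TPM, in which the authors scaled each library for gene length and to a common total. The submitters' processing notes list FastQC, Trim Galore, STAR 2.7.3a and RSEM 1.3.3 with no order or role, and 2 genome builds, GRCm39 and mm10. Which build and annotation release made these tables, and whether counting used the strand that the directional library kit marks, is not given in the sources used here. Genes are therefore given by symbol without coordinates, and antisense or overlapping genes are uncertain. Of 55416 gene identifiers, 52083 matched a name in GENCODE M21 and 3333 stayed unnamed. The unnamed identifiers took a mean of 0.628% of adult and 1.07% of fetal counts, and they remained in the library totals and tests.

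Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter by group, and a quasi-likelihood F-test of fetal against adult with no other term. Genes with a Benjamini-Hochberg adjusted p under 0.05 among the 14271 tested are called higher or lower. Values are CPM scaled with the TMM factors, 0.918 in each adult library and 1.10 and 1.08 in the fetal libraries. Errors of log2 fold changes are standard errors, and errors of group means are SD over 2 libraries. Where every library of a group had 0 counts, the fold is a lower bound computed against a floor of 3 counts per library. Where a group held 1 to 3 counts in all, the ratio of the summed counts is given with its exact 95% interval (Clopper-Pearson on the split of the counts). Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. A floor of 3 counts corresponds to 0.23 to 0.276 CPM of the unscaled library totals.

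The lists, the rule for named genes, the tests and the alternatives below were fixed before the data were examined. There were 19 gene lists of intestinal biology and 10 lists of other cell types or of sample quality, with 493 members in all. Of these, 492 were found; Muc6 was not matched. Lists with at least 2 tested members, 27 in all, were compared with the other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Calls of list members were also counted with p adjusted over the list alone.

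The genes named were set by rule. They are Ptgs1, which the series title names, and the 8 largest rises and 8 largest falls among called genes with a named symbol that is not a predicted gene model, a mean of at least 10 CPM in the higher group and no overlap of the groups. In each of the 19 lists they are up to 3 called members in the direction with more calls and 1 in the other, at 1 CPM or more in the higher group, and in each of the 10 other lists the 2 most abundant members. Copies of multigene families count as uncertain. The rule gave 102 genes, and any other gene named was chosen after its values were seen. Some genes that the rule gave are not reported here.

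Replicates were compared first. Within groups the chi-square per degree of freedom over genes with at least 20 counts was 3.30 for adult and 2.81 for fetal, above sampling noise in both, so all 4 libraries were counted separately. The edgeR steps were tested on data simulated from these libraries over 14028 genes, with 50 genes changed at each of 4 fold sizes. They recovered 48% of changes of 1.25-fold, 62% of 1.5-fold, 74% of 2-fold and 100% of 4-fold, and 9.55% of the calls were false, above the nominal 5%. DESeq2 on the same simulated counts recovered 22%, 50%, 70% and 98% with 1.64% false calls, and limma on log2(TPM + 1) recovered 4%, 40%, 60% and 92% over 13840 genes with 16.2% false calls. Of 200 simulated lists without an effect, camera with the preset correlation gave p under 0.05 for 4%, camera with an estimated correlation for 0% and fry for 6.5%. Simulated genes varied independently and few of them were changed, so these rates need not hold for the real libraries.

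The counts of called genes were recomputed under 18 alternatives. They were DESeq2 size factors, upper-quartile scaling and library totals in edgeR; the DESeq2 1.42.0 Wald test; no filter and a stricter filter (1 CPM in 2 libraries and 10 counts in every library of a group); unrounded counts; limma on log2(TPM + 1) and log2(TPM + 0.1) for genes at 1 TPM or more in 2 libraries, and on log2(TPM + 1) without that filter; edgeR's glmTreat against a fold of 1.5; an adjusted p under 0.01; a fit without mitochondrial genes and the 20 genes with most counts; a replicate block; and each library left out in turn. The lists were retested under 10 alternatives. With an estimated correlation camera called no list, including lists whose estimate lay below the preset of 0.01. Its p-values in that setting therefore do not measure an effect of correlation between genes. TPM fold changes are on the log2(value + pseudocount) scale, which understates changes of low genes. Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1 was used for the summaries.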

Results

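RNA-seq profiles of mouse small intestinal organoids from adult animals (n = 2 libraries) and from mouse embryos (n = 2 libraries) were compared. The series title concerns partial reprogramming, regeneration of the intestine and induction of Ptgs1, and this part of the series sets the fetal epithelial state against the adult one. The adult libraries held 12449681 and 10862147 estimated counts over genes, and the fetal libraries 13061585 and 12184259. At least 1 count was found for 20502 and 20209 genes in the adult libraries and for 22081 and 22209 genes in the fetal libraries.

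Most fetal, regenerative and basement-membrane genes were higher in fetal organoids, some of them nearly silent in adult organoids, and most genes of mature absorptive and hormone-producing cells were lower. Spp1, a secreted matrix protein, stood at 192 ± 3.11 CPM (SD, n = 2) in fetal and 0.144 ± 0.0800 CPM in adult organoids, and Igf2bp1, an oncofetal RNA-binding protein, at 91.4 ± 0.644 CPM against 0 counts. In the other direction, Pigr, which carries immunoglobulin A across the epithelium, fell from 1723 ± 31.8 to 7.26 ± 4.05 CPM (log2 fold change -8.62 to -7.405 with single libraries left out). Fabp1, a fatty acid carrier of enterocytes, fell from 117 ± 4.25 to 0.66 ± 0.143 CPM. Lgr5, the marker of crypt stem cells, differed little, at 269 and 275 CPM in the adult and 220 and 224 CPM in the fetal libraries (log2 fold change -0.30 ± 0.03 SE); it was chosen after its values were seen.

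Of 14271 genes tested, 9497 (66.5%) changed between fetal and adult organoids, 4833 higher and 4664 lower in fetal (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). These calls rest on a small spread between the libraries of a group, which may be technical (common coefficient of variation beyond counting noise in edgeR, 0.033). At least 2-fold changes numbered 1943 higher and 1662 lower, and at least 4-fold changes 1175 and 816. The libraries of the groups did not overlap for 11800 genes (82.7%), where chance alone gives 33.3%. The library profiles correlated across genes, which are not independent replicates, at 0.989 within adult and 0.991 within fetal, and at 0.829 to 0.835 between groups. In the same edgeR test the balance of the calls changed little with other scaling factors. DESeq2 size factors gave 4883 genes higher and 4607 lower, and upper-quartile scaling 4904 and 4578. Leaving out mitochondrial genes and the 20 genes with most counts gave 4815 and 4631. Library totals without such factors shifted the balance to 6979 higher and 2973 lower. With limma on log2(TPM + 1), where unit, test and filter all differ, 6957 were higher and 1796 lower. The median log2 fold change of all genes was 0.01 with TMM, 0.25 with library totals and 0.36 on TPM, and mitochondrial transcripts took 17.5% ± 0.0552 (SD, n = 2) of adult and 7.40% ± 0.594 of fetal counts.

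**Figure D1:**
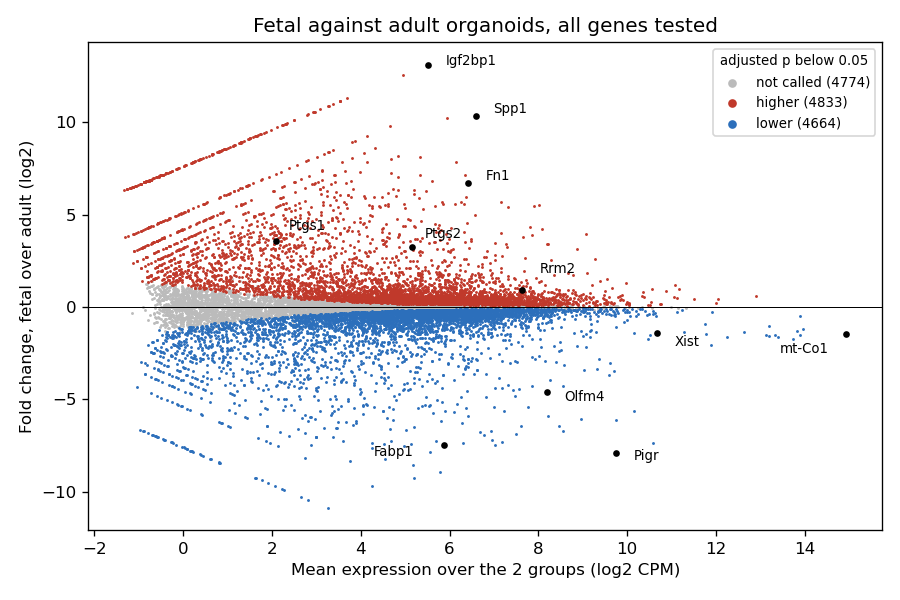
Fold change of each tested gene (log2, fetal over adult; y axis) against its mean expression over the groups (log2 CPM; x axis), coloured by the edgeR call: 4833 genes higher and 4664 lower in fetal. Genes at 0 in 1 group form the outermost slanted lines, where the fitted value depends on the prior count and is no bound.

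Ptgs1, the constitutive cyclooxygenase (ENSMUSG00000047250), rose 11.7-fold in fetal organoids, from 0.671 ± 0.329 to 7.82 ± 0.783 CPM (SD, n = 2; log2 fold change 3.55 ± 0.32 SE, edgeR, Benjamini-Hochberg adjusted p = 7.13e-07). Its counts were 5 and 9 in the adult libraries and 104 and 110 in the fetal libraries. Ptgs2, the inducible cyclooxygenase, rose 9.34-fold from 6.88 to 63.9 CPM. Ptges, the microsomal prostaglandin E synthase, had 2 counts in adult and 134 in fetal organoids, a ratio of 52.2 (95% counting interval 14.2 to 435). Cbr1, a carbonyl reductase that acts on prostaglandin E2, fell from 129 to 21.8 CPM (log2 fold change -2.56 ± 0.06 SE). Hpgd and Ptgr1, which inactivate prostaglandins, also fell, by 1.87 and 2.53 on the log2 scale (both chosen after their values were seen). Of the 15 tested genes of prostaglandin synthesis, breakdown, receptors and transport, 6 rose, 5 fell and 4 were not called, with the same counts adjusted over the list alone. The list as a whole did not stand apart from other genes (camera, Benjamini-Hochberg adjusted p = 0.94); its median log2 fold change was -0.27, its mean 0.37, and the median was 0.36 on log2(TPM + 1).

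All 21 genes of the fetal and regenerative list rose. Besides Spp1 (ratio 1370, 95% counting interval 467 to 6630), the leading members were Gja1, a gap-junction protein (123 ± 2.54 CPM in fetal, ratio 1320, interval 364 to 10900), and Ereg, a ligand of the epidermal growth factor receptor (50.8 ± 1.54 CPM, ratio 1090, interval 194 to 42900). The list was higher than other genes (camera, Benjamini-Hochberg adjusted p = 2.84e-10; adjusted p = 0.244 with an estimated correlation). In the oncofetal list 10 of 11 tested genes rose: Igf2bp1 was at least 324-fold higher, the imprinted RNA H19 at least 73.9-fold, and Peg3, an imprinted zinc-finger gene, rose from 3.30 to 156 CPM. Afp, the fetal serum protein, was the exception and fell from 3.59 to 0.809 CPM (log2 fold change -2.15 ± 0.36 SE). The oncofetal list had a camera adjusted p (Benjamini-Hochberg) of 0.000338, and adjusted p = 0.271 with an estimated correlation.

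Genes known as targets of the transcriptional co-activator YAP rose in 18 of 20 cases. Ccn2, a matricellular protein, rose from 1.15 ± 0.64 to 160.5 ± 1.18 CPM (log2 fold change 6.63 to 7.81 with single libraries left out). Ccdc80 was at least 19.7-fold higher and Fjx1 at least 5.92-fold higher. Nuak2 fell from 16.2 to 8.74 CPM; on TPM with limma its adjusted p (Benjamini-Hochberg) was 0.067 to 0.145. The list's median log2 fold change was 2.79 as fitted and 2.56 with genes at 0 in adult set at their bound (camera, Benjamini-Hochberg adjusted p = 2.01e-06; adjusted p = 0.271 with an estimated correlation). Of 19 matrix and adhesion genes, 17 rose. Tnc, tenascin C, was at least 30.9-fold higher, Lamb1, a laminin chain, rose from 0.571 to 80.0 CPM, and Fn1, fibronectin, from 1.66 ± 0.357 to 169.5 ± 0.34 CPM (SD, n = 2). The integrin Itga2 fell from 76.4 to 22.2 CPM (camera for the list, Benjamini-Hochberg adjusted p = 2.95e-06; adjusted p = 0.271 with an estimated correlation). Beside these lists, 8 of 10 tested mesenchymal markers also rose, led by Col3a1 at 26.0 ± 0.646 CPM in fetal against 0 counts in adult. Counts adjusted over the list alone were the same for these 4 lists.

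Transcripts of mature enterocytes, the absorptive cells, fell in 28 of 29 cases. Besides Fabp1, the trehalose-cleaving enzyme Treh had 1 count in fetal against 164 in adult organoids (ratio 211, 95% counting interval 37.3 to 8370). The amino acid transporter Slc6a19 fell from 24.2 ± 2.25 to 0.152 ± 0.215 CPM (0 and 4 counts in fetal; log2 fold change -11.18 to -6.26 with single libraries left out). Krt20, a keratin of differentiated cells, went the other way, from 24.1 ± 1.58 to 86.7 ± 0.977 CPM. All 24 genes of xenobiotic metabolism fell, with a median log2 fold change of -4.67. The cytochromes Cyp3a25 (ratio 666, interval 227 to 3230) and Cyp2c29 (257 to 1.48 CPM; log2 fold change -8.14 to -6.96 with single libraries left out) and the alcohol dehydrogenase Adh6a (ratio 201, interval 55.2 to 1670) led. Camera gave Benjamini-Hochberg adjusted p = 4.47e-10 for enterocytes and 1.79e-11 for xenobiotic metabolism (adjusted p = 0.244 and 0.29 with an estimated correlation). Enteroendocrine genes fell in 19 of 20 cases: Tph1, the serotonin-synthesis enzyme, had 2 counts in fetal against 157 in adult (ratio 101, interval 27.5 to 840). The hormone gene Gip fell from 22.3 ± 0.419 to 0.301 ± 0.327 CPM, and the tachykinin gene Tac1 fell to 0.371 ± 0.229 CPM (log2 fold changes -8.125 to -5.353 and -5.78 to -4.46 with single libraries left out). Cpe, a peptide-processing enzyme, rose from 18.4 to 61.5 CPM (camera for the list, Benjamini-Hochberg adjusted p = 7.75e-07; adjusted p = 0.271 with an estimated correlation). The counts of these 3 lists were the same adjusted over the list alone.

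Of 13 goblet cell genes, 8 fell, 2 rose and 3 were not called; adjusted over the list alone 9 fell and 2 rose. Fcgbp and Muc2, components of mucus, fell from 1425 ± 53.8 to 111 ± 0.573 CPM and from 504 ± 8.26 to 67.5 ± 9.56 CPM, and the kallikrein Klk1 from 5.14 to 0.619 CPM, whereas Clca1 rose from 1.24 to 5.92 CPM (camera, Benjamini-Hochberg adjusted p = 0.00801; adjusted p = 0.271 with an estimated correlation). Of 15 Paneth cell genes, 9 fell, 4 rose and 2 were not called, also adjusted over the list alone. The lectin Itln1 fell from 581 to 37.3 CPM, the defensins Defa30 and Defa26 fell by 4.10 and 3.92 on the log2 scale (uncertain, since alpha-defensin copies share reads), and the matrix protease Mmp7 rose from 6.19 to 74.2 CPM. Defa26 had 0 and 5 counts in the fetal libraries and ranged from -8.12 to -2.90 with single libraries left out. The Paneth list passed camera narrowly (Benjamini-Hochberg adjusted p = 0.0435). It did not pass without adult replicate 2 (adjusted p = 0.0751), without fetal replicate 1 (0.06), with the replicate number as a block (0.0706) or on ranks (0.0582), and had adjusted p = 0.341 with an estimated correlation, the highest of 10 alternatives that began at 0.000363. Of 11 tested tuft cell genes 4 rose, Ptgs1 among them, 3 fell and 4 were not called, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.94). With single libraries left out, 3 to 4 tuft genes were higher and 1 to 2 lower. Alox5 had 3 counts in adult and 40 in fetal (ratio 10.4, interval 3.31 to 52.5), Ltc4s rose from 0.42 to 1.35 CPM, and Trpm5, the cation channel of tuft cells, had 27 counts in adult and 3 in fetal (ratio 11.6, interval 3.56 to 59.5). The Ltc4s call was lost without adult replicate 1, adult replicate 2 or fetal replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.0661, 0.0705 and 0.0731).

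**Figure D2:**
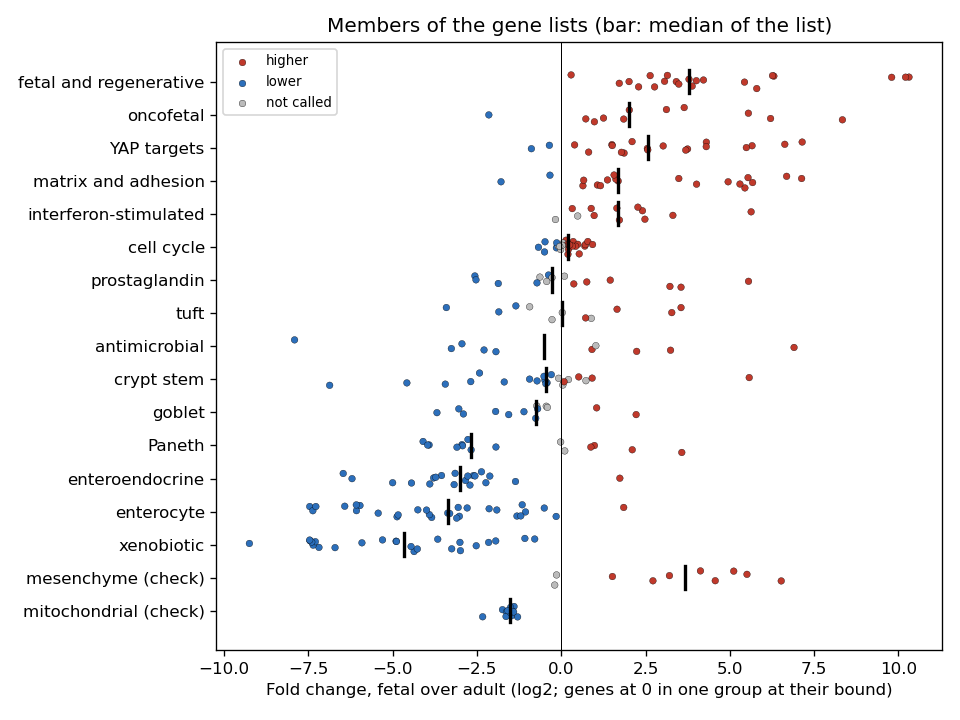
Fold change (log2, fetal over adult; x axis) of each tested member of 17 gene lists (rows), coloured by the edgeR call, with a bar at the list's median; members at 0 in 1 group are drawn at their bound. All 21 fetal and regenerative genes lie to the right of 0 and all 24 xenobiotic genes to the left.

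Crypt stem cell genes fell in 13 of 21 cases, with 4 higher and 4 not called. Aqp4, a water channel, fell from 359 ± 2.40 to 3.10 ± 1.43 CPM, Olfm4 from 560 ± 3.51 to 23.5 ± 2.66 CPM and Rgmb from 180 to 16.6 CPM, while Tnfrsf19, a receptor of the tumour necrosis factor family, rose from 2.83 ± 0.589 to 136.5 ± 0.0298 CPM (SD, n = 2). The list was lower than other genes (camera, Benjamini-Hochberg adjusted p = 0.0356; adjusted p = 0.29 with an estimated correlation), and its median log2 fold change of -0.46 was -0.06 on log2(TPM + 1), where 7 members were higher and 7 lower. Of 25 cell cycle genes, 15 rose, 5 fell and 5 were not called, all by less than 2-fold. With library totals 22 were higher and 3 lower, and on log2(TPM + 1) 22 and 1. Rrm2 rose from 136 to 259 CPM, Mcm4 from 151 to 261 CPM and Mcm3 from 121.8 to 199.8 CPM, genes of DNA synthesis, and the mitotic motor Kif11 fell from 214.5 to 134.2 CPM; the list did not pass camera (Benjamini-Hochberg adjusted p = 0.0922). The 2 tested reprogramming factors rose, Klf4 from 18.6 to 88.1 CPM and Myc from 60.2 to 99.2 CPM, without the pair passing camera (Benjamini-Hochberg adjusted p = 0.0751). Counts for these 3 lists were the same adjusted over the list alone.

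**Figure D3:**
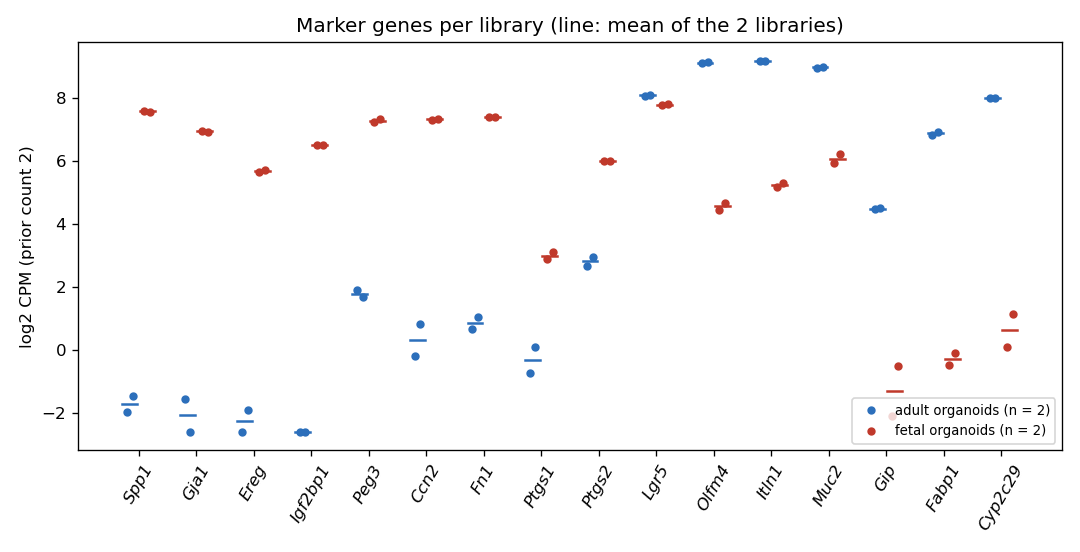
Expression of 16 genes per library (log2 CPM with a prior count of 2; y axis), with adult libraries in blue, fetal libraries in red and lines at the mean of 2 libraries. Ptgs1 lies at 0.671 CPM in adult and 7.82 CPM in fetal organoids, and Lgr5 is the gene of this set whose groups lie closest.

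Interferon-stimulated genes rose in 10 of 12 cases and none fell. Ifit1 had 1 count in adult and 77 in fetal (ratio 59.9, 95% counting interval 10.4 to 2400), Rtp4 had 3 and 41 (ratio 10.6, interval 3.39 to 53.7), and the chemokine Cxcl10 rose from 0.52 to 2.93 CPM, so that these genes stayed at low levels (camera, Benjamini-Hochberg adjusted p = 0.00222; adjusted p = 0.271 with an estimated correlation). Antimicrobial and defence genes moved both ways, 4 higher and 5 lower of 10, or 5 and 5 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.71). Beside Pigr, Lypd8 fell by 3.26 on the log2 scale and the lectin Reg3a, with 23 counts in adult and 0 in fetal, was at least 4.89-fold lower. The related Reg3b and Reg3g rose, by 2.24 and 0.91 on the log2 scale (both chosen after their values were seen). Saa3, an acute-phase protein, had 1 count in adult and 187 in fetal (ratio 146, interval 25.8 to 5780). Of 7 tested antigen presentation genes, 3 rose (Tap1 from 8.11 to 16.6 CPM, H2-D1 from 92.7 to 152.5 CPM and Tapbp from 30.4 to 44.9 CPM), B2m fell from 154.5 to 75.2 CPM, and 3 were not called (camera, Benjamini-Hochberg adjusted p = 0.579). The interferon and antigen presentation counts were the same adjusted over the list alone. With library totals, 5 antigen presentation genes were higher and 1 lower.

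Cholesterol synthesis genes divided into 8 higher, 9 lower and 4 not called of 21, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.88). Insig1, a sterol sensor partner, fell from 273 to 123 CPM and the reductase Dhcr7 from 103 to 61.4 CPM. The median log2 fold change of the cholesterol list was 0.01 and its mean -0.06. With library totals 12 of its genes were higher and 3 lower (median 0.26), and on log2(TPM + 1) 15 and 2 (median 0.36). Genes that pattern the intestine along its length gave 5 higher and 4 lower of 12, or 6 and 4 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.982). Slc40a1, the iron exporter of the proximal intestine, rose from 3.87 to 53.5 CPM, Slc10a2, the bile acid transporter of the ileum, from 1.62 to 9.14 CPM, Hoxb6 was at least 4.86-fold higher, and Onecut2, a transcription factor of the proximal intestine, fell from 211 to 30.5 CPM.

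The largest rises by the fixed rule were Igf2bp1, the embryonic claudin Cldn6 (at least 219-fold, 61.7 ± 0.804 CPM), the collagen Col3a1 (at least 92-fold), 4 copies of pancreatic amylase (Amy2a2, Amy2a3 and Amy2a4 at least 82.3-fold each, Amy2a1 at least 68.8-fold) and H19. All of these had 0 counts in adult, so their rank rests on fitted values that depend on the prior count. Their bounds lie below the ratios of Spp1 and Gja1 given above, so a larger rise than in those genes is not shown. The amylase copies are near-identical and Amy2a2, Amy2a3 and Amy2a4 held the same estimated counts, 325 and 311, so their individual values are uncertain. The largest falls included Cfhr2, a complement factor H relative (at least 88-fold, from 19.3 ± 0.729 CPM), the organic anion transporter Slco2b1 (ratio 1040, 95% counting interval 187 to 41300) and Cyp3a25. Others were the inflammatory caspase Casp1 (72.4 ± 4.97 to 0.19 ± 0.269 CPM; log2 fold change -12.76 to -7.53 with single libraries left out), the arginase Arg2 (ratio 373, interval 103 to 3080), the ketosteroid reductase Akr1c14 (46.2 to 0.149 CPM; -9.18 to -7.59) and Agr3 (ratio 365, interval 64.9 to 14500). Each of these rises and falls passed edgeR with a Benjamini-Hochberg adjusted p of 3.32e-09 or less. Of the genes with 1 to 3 counts in a group given with a counting interval in this text, all but Arg2, Tph1 and Trpm5 moved by over 1.5-fold when a single library was left out, most widely Alox5 (log2 fold change 2.23 to 7.24).

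Among markers of other cell types, besides Col3a1, Col1a1 rose from 0.376 ± 0.0361 to 17.5 ± 0.236 CPM; of the 10 tested mesenchymal markers 8 rose and 2 were not called (camera, Benjamini-Hochberg adjusted p = 0.000539; adjusted p = 0.271 with an estimated correlation), with a median log2 fold change of 4.82 as fitted and 3.67 with bounds. Of 5 tested stomach and squamous genes 4 rose, Vsig1 from 3.88 to 41.3 CPM, and Anxa10 was not called at 18.8 and 17.2 CPM (camera, Benjamini-Hochberg adjusted p = 0.0423; adjusted p = 0.294 with an estimated correlation; median log2 fold change 3.40 as fitted and 1.99 with bounds). The stomach list did not pass without fetal replicate 1 or on log2(TPM + 1) (camera, Benjamini-Hochberg adjusted p = 0.141 and 0.113), and with single libraries left out 2 to 5 of its genes were higher. The immune genes Cd68 and Lyz2 rose from 1.99 to 7.14 and from 0.37 to 3.27 CPM, while the other 20 immune markers were too low to test (camera for the pair, Benjamini-Hochberg adjusted p = 0.0922). Of 2 endothelial genes Egfl7 was called higher (2.15 to 3.88 CPM) and Esam was not called (camera, Benjamini-Hochberg adjusted p = 0.982); the Egfl7 call was lost without adult replicate 1 or fetal replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.291 and 0.148). The 3 tested neural genes fell, among them Ret from 9.56 to 1.56 CPM (camera for the list, Benjamini-Hochberg adjusted p = 0.0751; 0.0153 on log2(TPM + 1) and 0.0402 without fetal replicate 2). Upk3b, of 6 mesothelial markers the one tested, fell from 3.27 to 0.447 CPM (log2 fold change -3.91 to -2.23 with single libraries left out); Bnc1 had 0 counts in adult and 3 in fetal. None of 8 erythroid genes was high enough to test: Alas2 had 3 counts in adult and 5 in fetal organoids, and Hba-a2 had 0 and 5. Counts for the cell type lists were the same adjusted over the list alone.

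Dissociation and stress genes moved both ways, 7 higher, 6 lower and 2 not called of 15 (camera, Benjamini-Hochberg adjusted p = 0.831); their median log2 fold change of -0.01 was positive with library totals (0.23) and TPM (0.36), and their mean was 0.66. Fos fell from 213.5 to 145.2 CPM. Egr1 fell by 0.22 on the log2 scale, but its fold change was positive with library totals and TPM. All 13 mitochondrially encoded genes fell under every scaling run, among them mt-Co1 from 45880 ± 210 to 16440 ± 815 CPM and mt-Cytb from 22670 ± 26.6 to 7956 ± 692 CPM (camera for the list, Benjamini-Hochberg adjusted p = 8.19e-06; adjusted p = 0.294 with an estimated correlation). Of 5 sex-linked genes, 4 Y-linked genes rose and Xist, the RNA of the inactive X chromosome, fell from 2365 ± 7.26 to 889.6 ± 25.95 CPM (camera for the list, Benjamini-Hochberg adjusted p = 0.0628; 0.0367 and 0.0351 without adult replicate 1 or 2). The Y-linked Eif2s3y had 1 count in adult and 569 in fetal organoids (ratio 443, 95% counting interval 79.2 to 17500). Counts for these 3 lists were the same adjusted over the list alone.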

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

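None of the alternatives reported here was chosen after results were seen. The 11 called core lists lost their call with an estimated correlation in camera. The adjusted p (camera) was 0.244 for the fetal and regenerative list and for enterocytes. It was 0.271 for the oncofetal, YAP, matrix, goblet, enteroendocrine and interferon lists, 0.29 for crypt stem and xenobiotic, and 0.341 for Paneth. In that setting the test on simulated lists called 0% of lists without an effect. A simulated list of changed genes had an unadjusted p of 0.0114 (camera), against 4.84e-32 with the preset correlation. Simulated genes varied independently, so the setting loses power even without correlation, and its behaviour with correlated genes is not shown. In these data the fetal and regenerative, crypt stem, goblet, enterocyte, interferon and matrix lists had negative estimates (-0.0594 to -0.00199), below the preset 0.01. The other called core lists had estimates of 0.0601 to 0.319. The lost calls therefore do not show that correlation between genes undoes them. Over lists and settings 233 of 270 list tests gave the same outcome, called or not called, as did 1718 of 1766 values of named genes. The DESeq2 Wald test gave 7848 genes changed, 4074 higher and 3774 lower, and did not call 1650 of the 9497 genes. It had fewer false calls than edgeR on simulated data (1.64% against 9.55%). Far fewer genes were changed there than were called here, so those rates need not hold for these calls. glmTreat against a 1.5-fold change gave 4059 genes changed, 2137 higher and 1922 lower, by its stricter null hypothesis. The lower count was 4607 with DESeq2 size factors and 4578 with upper-quartile scaling. It fell to 2973 with library totals, and on TPM with limma to 1796, to 1752 with a pseudocount of 0.1 and to 1728 without a filter. The TPM settings change unit, test and filter together. Leaving out single libraries gave 8631 to 8920 genes changed, 4447 to 4583 higher and 4181 to 4463 lower, and a Paneth adjusted p of 0.0157 to 0.0751; the arm left with 1 library was assumed to vary like the other. The labels give both groups replicates 1 and 2. Their deviations did not pair (correlation -0.01 across genes), and with the replicate number as a block 9349 genes changed (4765 higher, 4584 lower) and the Paneth adjusted p was 0.0706. It was 0.0582 on ranks. By fry, which tests a list by itself, calls were gained for the prostaglandin (down, 0.00297), antimicrobial (down, 0.000286), antigen presentation (up, 0.0477), cell cycle (up, 0.00588), cholesterol (down, 0.0356), reprogramming (up, 0.00191), immune (up, 0.000953), neural (down, 0.0016), stress (up, 0.00116) and sex-linked lists (up, 0.00191), and the patterning list turned down (0.00116). On log2(TPM + 1) camera called the antimicrobial (0.0268), cell cycle (0.0261) and neural lists (0.0153) and did not call the stomach list (0.113). Anxa10 turned positive with library totals (0.12) and TPM (0.34 with pseudocount 1, 0.36 with 0.1, 0.34 without a filter), Esam with TPM (0.32, 0.42 and 0.32) and Egr1 with library totals (0.023) and TPM (0.165, 0.166 and 0.165). These are log2 fold changes; for these and the other differences the cause was not tested. Depth limits genes under about 10 counts: 27364 genes had a count and 14271 passed the filter.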

Other observations

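The gene groups in the first 2 paragraphs, and the tests of library scaling, stress, mesenchymal cells, matrix genes and Xist, were chosen only after results were seen; the tests of nuclear-encoded respiratory subunits, of chromosomes X and Y and of pancreatic enzymes were set before their results were seen. The 18 groups were adjusted together. That adjustment does not allow for choosing groups on the same values, so the p-values of the groups chosen late describe them and are no independent support. Imprinted genes were higher in fetal organoids in 16 of 20 tested cases and lower in none (camera, Benjamini-Hochberg adjusted p = 8.66e-06; adjusted p = 0.137 with an estimated correlation), and 11 of the 14 not on a fixed list were higher. Grb10, an adaptor that restrains growth-factor signalling, rose from 0.614 to 140 CPM (log2 fold change 7.83 ± 0.12 SE), and Usp29 and Plagl1 also rose, while Gnas was not called at 354 and 343 CPM. Keratins were higher in 16 of 17 cases, from the abundant Krt8 (log2 fold change 0.98) and Krt7 (3.15) to Krt6a, which had 0 and 1 counts in the adult and 524 and 444 in the fetal libraries. Collagens were higher in 15 of 18 cases, with Col4a1 rising from 11.0 to 508 CPM and Col4a2 from 10.7 to 470 CPM. Of the 18 collagens 5 are on fixed lists, Col1a1, Col1a2 and Col3a1 among the mesenchymal markers and Col4a1 and Col4a2 among the matrix genes; outside them 10 of 13 were higher. Outside the fixed lists 13 of 14 keratins, 6 of 8 S100 genes and 5 of 6 Wnt ligands were higher. Of 9 S100 genes 7 were higher and S100g, a calcium-binding protein of enterocytes, fell from 38.0 to 0.19 CPM. Of 16 serpins 11 were higher and 4 lower, and of 7 Wnt ligands 5 were higher, among them Wnt7b with 1 and 1 counts in the adult and 175 and 166 in the fetal libraries, while Wnt3 fell from 5.99 to 0.692 CPM. Camera gave Benjamini-Hochberg adjusted p = 1.18e-06 for keratins, 2.58e-07 for collagens, 0.00572 for S100, 0.00795 for serpins and 0.0569 for Wnt ligands (adjusted p = 0.137 with an estimated correlation for the first 4 and 0.329 for the last).

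Most genes of the detoxifying families fell: 12 of 12 UDP-glucuronosyltransferases, 20 of 20 glutathione S-transferases, 10 of 11 carboxylesterases (1 rose) and 30 of 35 cytochromes P450 (5 rose). Camera gave Benjamini-Hochberg adjusted p = 7.93e-07, 3.27e-08, 2.5e-05 and 3.27e-08 in that order, and 0.137 for each with an estimated correlation. The medians of these families were below 0 under library totals and TPM as well. Outside the fixed lists 16 of 16 glutathione S-transferases, 7 of 8 carboxylesterases and 21 of 26 cytochromes P450 fell. All 4 tested butyrophilin-like genes, which engage intraepithelial T cells, fell, Btnl1 from 38.0 to 0.222 CPM and Btnl4 from 19.9 to 0.333 CPM (camera, Benjamini-Hochberg adjusted p = 0.00567; adjusted p = 0.157 with an estimated correlation). Proteasome subunits were higher in 36 of 45 cases by a median log2 fold change of 0.36 (camera, Benjamini-Hochberg adjusted p = 0.000141; adjusted p = 0.137 with an estimated correlation). Ribosomal protein genes (6 higher, 56 lower of 72, median -0.18) turned positive with library totals (0.07) and TPM (0.21). Zfp zinc-finger genes (52 higher, 167 lower of 353, median -0.30) turned positive on TPM (0.08). Neither direction held across TMM, library totals and TPM, and other scaling factors were not run for these groups. Solute carriers (64 higher, 100 lower of 214; median -0.20) also turned positive in both (0.04 and 0.13). Of 10 claudins 5 were higher and 2 lower, with Cldn4 rising from 24.9 to 205 CPM and Cldn15 falling from 153 to 1.97 CPM. Solute carriers and claudins did not pass camera (Benjamini-Hochberg adjusted p = 0.0569 and 0.143). Genes of the X chromosome had a median log2 fold change of 0.07 over 452 tested genes, and autosomal genes 0.00.

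Mitochondrially encoded transcripts were lower in fetal organoids in all 13 genes. With library totals alone the median log2 fold change was still -1.265, so the fall did not turn on the choice between TMM and library totals. This met the bound written against scaling by a few abundant genes as the cause. It cannot decide that question, because dropping the TMM factors shifts all genes alike, by too little to reach the other bound. Library totals also include the mitochondrial reads themselves. A lower respiratory programme would also lower the nuclear-encoded subunits: 62 of 75 were called lower and 1 higher, with a median of -0.417, between the bounds set for either outcome, and it shrank to -0.17 with library totals and -0.05 on TPM. More stress or damage in the adult cultures may also raise this share, and the stress list could not decide it, with a median of -0.014 over members that went both ways (Jun lower by 2.20, Hspa1a higher by 3.42 on the log2 scale). The developmental stage itself remains an open, untested explanation.

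Matrix and adhesion genes and mesenchymal markers were both higher in fetal organoids, and fetal cultures might hold mesenchymal cells despite their epithelial label. The 17 matrix and adhesion genes called higher include integrins and Cd44, which are cell-surface genes. They rose by a median of 127 CPM, 4.88 times the 26 CPM of Col3a1, the mesenchymal marker that rose most. Of the 17, 15 rose by more than Col3a1. The ratio met the bound written against such cells. It leaves the source of the rise open, because these libraries do not measure what mesenchymal cells express. For the markers themselves the question also stays open: the 11 markers too low to test summed to 2 and 6 counts in adult and 39 and 25 in fetal libraries, a CPM ratio of 5.95, but Tagln and Pdgfrb were not called, and expression by epithelial cells would give such counts too. That ratio met the bound written for mesenchymal cells; the further condition that every tested marker be higher was added after the values were seen.

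Y-linked transcripts summed over 4 genes were 6 and 9 counts in adult and 817 and 790 in fetal libraries, and Xist in the fetal libraries was 36.8% and 38.4% of the adult mean (37.6% on average). A pool of embryos of both sexes against adult females is a candidate explanation. Its bound was met, but that bound was wide and written after the values were seen. In adult organoids Xist stood at 2365 CPM, and Ddx3y, Eif2s3y and Uty had 0, 1 and 1 counts in all, with 13 for Kdm5d. These values argue against male adults. Both fetal libraries held Xist, at 871 and 908 CPM, together with the Y-linked transcripts. Cells of 1 sex are not expected to hold both, so this argues against fetal cultures of 1 sex. It does not show how the sexes came to be mixed. The labels do not give the sex, and a change of Xist with stage was not tested. Of the called genes with a chromosome, 318 of 9478 (3.36%) lie on X or Y, against 2.96% of the genes not called. Most calls are therefore of genes on other chromosomes. The share met the bound written against sex-linked genes as the direct source of the calls. That outcome was fixed in advance, since only 452 X-linked and 7 Y-linked genes were tested, and no conclusion is drawn from it. Effects of sex on autosomal genes cannot be separated from stage with these libraries.

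Of 28 pancreatic acinar genes other than the Amy2a copies, 19 (67.9%) exceeded 3 counts in both fetal libraries, but 10 of the 28 did so in both adult libraries, 2 are also on the goblet list, and Pnlip, Prss1, Ctrc and Ptf1a had 0 counts in all 4 libraries. The 28 include the trypsins Prss2 and Try4. Trypsin transcripts were part of the pattern that prompted the test, so the share is not independent of that pattern. The 67.9% met the bound written for pancreatic cells. The question stays open because a condition that no such gene be at 0 in both fetal libraries was added after the values were seen. Ctrb1, a chymotrypsinogen, was the most abundant that rose, from 1.65 to 33.0 CPM, while Pnliprp2 fell from 7.88 to 1.33 CPM (7 higher, 6 lower and 1 not called of 14 tested; camera, Benjamini-Hochberg adjusted p = 0.22).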
